A study of Mus musculus with 12 samples.

How the data were processed

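RNA was measured in dorsal root ganglion (DRG) neurons of C57BL/6 mice aged 3 months. The mice carried a floxed Ret allele with an EGFP reporter and Cre recombinase in the gene of the sodium channel NaV1.8 (Scn10a), so that EGFP marked neurons with an active Ret locus in which Cre had acted. Ganglia of lumbar levels L3, L4 and L5 (called L345) or of levels L6 and S1 (called L6S1) were pooled from male or from female mice, dissociated and sorted by EGFP fluorescence. Each of the 12 libraries came from its own pool of 2 to 8 mice and 12 to 32 ganglia, with 10 ng of RNA as input and 12 cycles of library PCR, per the labels' protocols. For male L345 C the labels give 5 mice in one field and 3 in another. Whether the pools of both levels came from the same mice is not given in the sources used here.

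The authors deposited 1 table per library with counts, CPM and RPKM for 41388 Ensembl genes. Reads were aligned with Subread and counted with featureCounts 1.4.5 on genome build GRCm38.p2, per the submitters' processing notes. The Subread version, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The deposited counts are whole numbers and were the only values tested. The deposited CPM equals the count scaled to the total of the same table in all 12 libraries, and the deposited RPKM equals that CPM per kilobase of the gene length in the table. Neither deposited CPM nor RPKM was used in a test. A GENCODE M21 annotation of the same mouse assembly gave a symbol for 40254 genes (97.3%), and its transcripts gave GC content and length for 15193 of the 15281 genes tested (99.4%).

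Total counts ranged from 16176436 (female L6S1 A) to 26694404 (female L345 D). A floor of 3 counts corresponded to 0.112 to 0.185 CPM. Reads carried no molecular identifiers, so this floor covers counting error only. No pair of libraries held identical counts, and the chi-square statistic per degree of freedom between libraries of one group was 10.6 to 140.0, so none was treated as a repeat of another.

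Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group (15281 genes kept) and a robust quasi-likelihood fit of 1 mean for each of the 4 groups (3 libraries each, 8 residual degrees of freedom). The common biological coefficient of variation was 0.239. The level contrast was the mean of the L6S1 groups minus the mean of the L345 groups with both sexes weighted equally. The sex contrast was female minus male with both levels weighted equally. The interaction was the level effect in females minus that in males. Each level effect within a sex and each sex effect within a level came from the same fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 by the edgeR quasi-likelihood F-test. Fold changes are given as log2 ± SE. An L6S1 library was counted as higher or lower for a gene when it lay above or below the mean of the L345 libraries of its sex. CPM values of genes are TMM-scaled, except the sex-label check and the summed marker levels of the closing section, which use each library's own total.

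Before the data were examined, 38 gene lists were fixed for DRG cell classes, contaminating cell types, channels, receptors, peptides and general processes, and 36 of them had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. The genes to be named were also fixed beforehand: for each contrast, among called genes with a mean of at least 2 CPM and one sign in both strata, the 10 largest changes per direction. Up to 4 called members per list, every gene of a contrast with few calls, and Ret, Scn10a, Mrgprd, Gfra2, Xist and the Y-linked genes were added. Gsta4, Srd5a2, Mrap2 and Pcsk1 fall outside this rule and were chosen after their values were seen.

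Other alternatives fixed beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of at least 1 CPM in at least 6 libraries, a term for the submission, the 8 libraries of the first submission alone, a replicate block, a glial score as covariate, and each library left out in turn. A fit without female L6S1 libraries B and C, a fit with per-library GC and length offsets (splines with 4 degrees of freedom), and a fit of the male libraries alone were added after seeing the data. The splits of the libraries numbered 100 for the level, sex and interaction contrasts and 10 for each contrast of 3 against 3 libraries, the real split included.

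The same code was tested on simulated counts with known changes. Of genes changed 2-fold, 69.7% were recovered for level, 75% for sex and 9.1% for the interaction. Of genes changed 4-fold, 97%, 96% and 69.4% were recovered. False calls made up 7.3%, 4% and 7.2% of all calls. These runs held 15052, 15042 and 15048 genes. Their counts were drawn independently for each gene, without GC or length bias and without outlying libraries, so the rates may not hold for the real libraries. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.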

Results

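Gene expression was compared in sorted Ret-lineage, NaV1.8-lineage sensory neurons from ganglia at L345 and at L6S1, in male and female mice. The 12 libraries formed 4 groups of 3: male L345 (A, B, C), female L345 (B, C, D), male L6S1 (A, B, C) and female L6S1 (A, B, C). Total counts were 20758857, 19756080 and 24813220 for male L345, 26182799, 25295739 and 26694404 for female L345, 25780213, 23862966 and 26460108 for male L6S1, and 16176436, 23362991 and 24782187 for female L6S1. Female L345 D, female L6S1 B, female L6S1 C and male L6S1 C belonged to a later submission than the other 8 libraries.

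The sorted cells carried the transcripts of small-diameter sensory neurons. Calca, which encodes the peptide CGRP, reached 7140 ± 1630 CPM (SD, n = 12), and Tac1, the substance P precursor, 2930 ± 751 CPM. Transcripts of the non-peptidergic class were abundant as well, with Rgs4 at 4820 ± 1030 CPM, Scn11a at 582 ± 134 CPM and the receptor gene Mrgprd between 370 ± 40.2 CPM (female L6S1) and 574 ± 77.9 CPM (male L345; SD, n = 3). The C low-threshold mechanoreceptor marker Th stood at 760 ± 192 CPM and the itch receptor gene Mrgpra3 at 95.7 ± 43.4 CPM (SD, n = 12). Of the neurofilament genes of large myelinated neurons, Nefh stood at 66.0 ± 20.8 CPM and Nefm at 485 ± 193 CPM. Glial transcripts were present too: Apoe had 942 ± 372 CPM and Pmp22 2700 ± 508 CPM. Hbb-bs, a red blood cell transcript, had 0.9 ± 0.678 CPM.

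The genes whose loci defined the sort did not pass the test between levels. Cells were sorted by EGFP, and Cre had acted on their floxed Ret allele, so Ret counts are no direct measure of the sort. Ret had 176 ± 27.5 CPM at L345 and 165 ± 33.6 CPM at L6S1 (SD, n = 6; log2 fold change -0.09 ± 0.15, edgeR adjusted p = 0.696). Scn10a had 573 ± 96.0 CPM and 429 ± 66.5 CPM (-0.42 ± 0.14, edgeR adjusted p = 0.101), and 6 of 6 L6S1 libraries lay below the L345 mean of their sex. The sex labels were checked with Xist, the transcript of X inactivation, which had at most 0.427 CPM in a male library and 15.4 to 69.1 CPM in the female libraries. Xist, Ddx3y, Eif2s3y, Kdm5d and Uty each placed 12 of 12 libraries on the side of their label.

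Libraries differed in composition within and between groups. Genes of the highest GC decile against those of the lowest lay at -0.93 (log2) in female L6S1 B and 0.59 in female L6S1 C, and between -0.46 and 0.56 in the other 10 libraries. Long against short transcripts lay between 0.12 and 0.50 in the L345 libraries except female L345 D (-0.26), and between -0.96 and 0.00 in the L6S1 libraries. Across 12972 genes, which are not independent replicates, the level fold change had a Spearman rho of -0.46 with transcript length and 0.04 with GC content. With the offsets for both, the rho with length was -0.05. The single gene Gm42418 took 1.27 to 2.03% of counts in the L345 libraries of the first submission, 0.68% in female L345 D and 0.25 to 0.7% in the L6S1 libraries. Spearman correlations between libraries of one group were 0.946 to 0.954 in female L6S1 and 0.982 to 0.994 in the other groups.

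**Figure D1:**
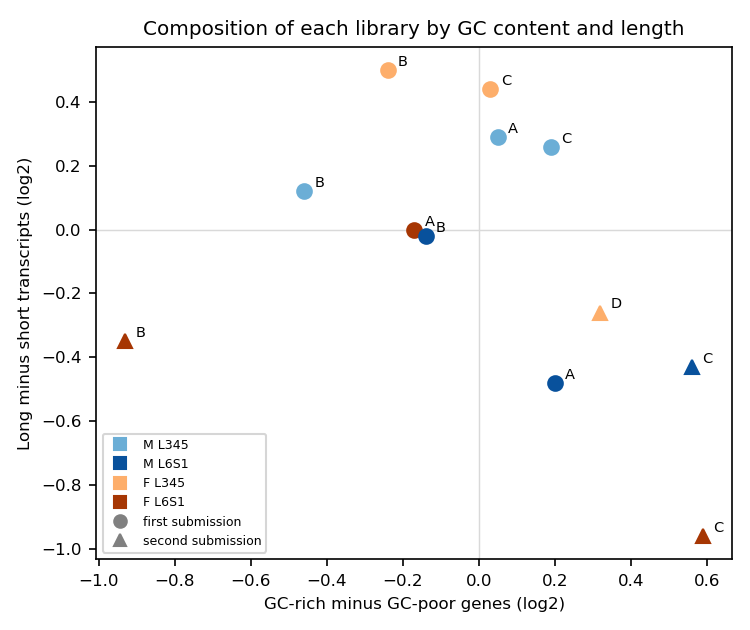
Composition of each of the 12 libraries: GC-rich minus GC-poor genes (x axis) against long minus short transcripts (y axis), by group (colour) and submission (shape). Each axis is the median of the highest decile minus that of the lowest, of log2 values relative to each gene's median over the libraries. The replicate letter stands beside each point. Female L6S1 B (-0.93) and female L6S1 C (0.59) lie at the ends of the x axis.

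The comparison of levels asked how neurons of the L6 and S1 ganglia, which include the afferents of the pelvic organs, differ from those of the L3 to L5 ganglia, which mainly serve the hindlimb. Caudal Hox genes, which mark position along the body axis, were higher at L6S1. Hoxd10 (ENSMUSG00000050368, chromosome 2, 74691924 to 74695105 on GRCm38.p2) rose from 6.59 ± 2.93 to 70.3 ± 12.8 CPM (SD, n = 6; log2 fold change 3.42 ± 0.34, edgeR adjusted p = 0.000105). Hoxd11 rose from 1.85 ± 1.02 to 20.5 ± 3.44 CPM (3.53 ± 0.35, edgeR adjusted p = 0.000112). The long non-coding RNA Hotair and Hoxc11 lay at or near the floor of 3 counts at L345, with 0.0705 ± 0.0997 and 0.108 ± 0.126 CPM, and had 2.8 ± 1.19 and 1.67 ± 0.642 CPM at L6S1. Each of these 4 genes was higher in 6 of 6 L6S1 libraries. With the 8 libraries of the first submission alone, Hoxd10 had an edgeR adjusted p of 0.0519.

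Of the 6 caudal Hox genes and transcripts tested, 5 rose and 1 (Hoxa10) did not pass. The count adjusted over the list alone was 5 higher and 1 lower. Their median log2 fold change was 3.47 (camera adjusted p = 8.49e-07, and adjusted p = 0.343 with an estimated correlation). Of 17 trunk Hox genes tested, 8 fell, 1 rose and 8 did not pass, with a median of -0.73 (camera adjusted p = 8.49e-07, and adjusted p = 0.133 with an estimated correlation). Hoxb7 (ENSMUSG00000038721, chromosome 11, 96286623 to 96290162) fell from 4.28 ± 0.919 to 0.51 ± 0.0986 CPM (-3.06 ± 0.23, edgeR adjusted p = 1.3e-05). Hoxb6 fell from 2.02 ± 0.457 to 0.381 ± 0.0914 CPM and Hoxb5 from 34.3 ± 6.31 to 14.3 ± 3.56 CPM. The trunk gene that rose was Hoxd9, from 3.39 ± 0.838 to 9.11 ± 1.98 CPM (1.43 ± 0.21, edgeR adjusted p = 0.00255). These 4 trunk genes kept their calls in every alternative run.

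A set of receptor, channel and peptide genes was higher at L6S1. Chrna3 (ENSMUSG00000032303, chromosome 9, 55011343 to 55026559) and its neighbour Chrnb4, whose products combine in nicotinic acetylcholine receptors, rose from 5.5 ± 1.51 to 45.9 ± 25.8 CPM and from 7.04 ± 1.58 to 36.4 ± 16.4 CPM (SD, n = 6). Their log2 fold changes were 2.96 ± 0.29 (edgeR adjusted p = 0.000105) and 2.31 ± 0.24 (edgeR adjusted p = 0.000112). Esr1, the estrogen receptor alpha gene (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), rose from 6.57 ± 2.22 to 26.4 ± 8.65 CPM (2.02 ± 0.22, edgeR adjusted p = 0.000176). Kcnk2, a two-pore potassium channel gene, rose from 13.3 ± 1.32 to 38.2 ± 9.89 CPM (1.51 ± 0.17, edgeR adjusted p = 0.000295). Penk, the enkephalin precursor (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), rose from 13.8 ± 6.58 to 75.2 ± 49.7 CPM (2.20 ± 0.28, edgeR adjusted p = 0.00112). Gal, the galanin precursor, rose from 229 ± 65.1 to 503 ± 76.7 CPM (1.14 ± 0.17, edgeR adjusted p = 0.00373). Qpct, whose enzyme modifies the ends of peptides, rose from 5.91 ± 1.18 to 34.0 ± 10.5 CPM (2.50 ± 0.20, edgeR adjusted p = 1.64e-05). Qrfpr, a neuropeptide receptor gene, rose from 1.27 ± 0.506 to 6.2 ± 2.43 CPM. All 8 genes were higher in 6 of 6 L6S1 libraries and passed in every alternative run.

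**Figure D2:**
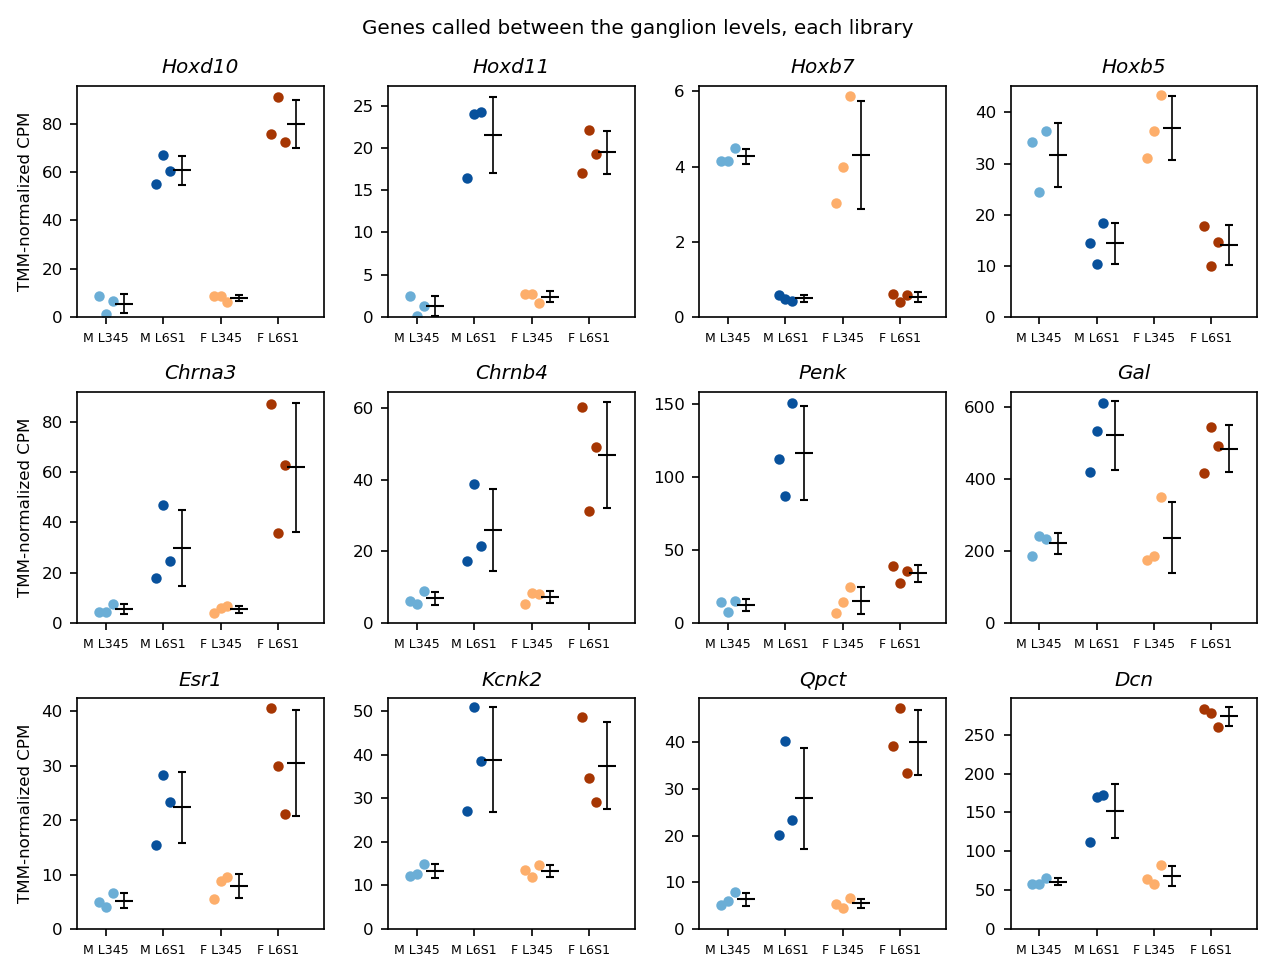
TMM-normalised CPM (y axis, linear) of 12 genes called between the levels in each library; points are libraries of the 4 groups and bars show mean ± SD (n = 3). Hoxd10 lies between 1.01 and 8.62 CPM in the L345 libraries and between 55.0 and 91.2 CPM in the L6S1 libraries.

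These receptor changes were not shared by the lists that hold the genes. Of 21 ligand-gated channel genes, 3 rose (Chrna3, Chrnb4 and Htr3a), 1 fell (Piezo2) and 17 did not pass, and the list did not pass (camera adjusted p = 0.448). Of 17 sex steroid and hormone receptor genes, Esr1 rose and 16 did not pass (camera adjusted p = 0.859). Of 79 potassium channel genes, Kcnk2 rose, Kcng1 fell and 77 did not pass (camera adjusted p = 0.118, and 0.0438 by camera without male L345 B). Of 12 genes of the opioid and cannabinoid system, Penk and Cnr1 rose and Oprd1 fell (camera adjusted p = 0.892). The calls of Htr3a (1.11 ± 0.25), Piezo2 (-0.76 ± 0.16), Kcng1 (-1.16 ± 0.26), Cnr1 (0.73 ± 0.17) and Oprd1 (-1.18 ± 0.25) were each lost in 6 to 9 of the 12 fits that left out 1 library. The edgeR adjusted p in those fits was at most 0.1 for Htr3a, 0.0993 for Piezo2, 0.104 for Kcng1, 0.114 for Cnr1 and 0.0978 for Oprd1, and all 5 passed without female L345 D and without female L6S1 A.

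The lists of peptidergic and of Mrgprd-class nociceptor genes passed by camera with medians of opposite sign, while most of their genes did not pass alone. Of 19 peptidergic genes tested, 4 rose (Gal, Tac1, Trpv1 and Cartpt) and 15 did not pass. The count adjusted over the list alone was 8 higher and 1 lower. The list's median was 0.40 (camera adjusted p = 0.00282, and adjusted p = 0.36 with an estimated correlation). It was 0.19 with 2 genes called without female L6S1 B and C, and 0.25 with the GC and length offsets. Tac1 rose from 2350 ± 145 to 3520 ± 630 CPM (SD, n = 6; 0.58 ± 0.12, edgeR adjusted p = 0.0282), and Trpv1, the capsaicin receptor gene, from 543 ± 90.6 to 779 ± 81.9 CPM (0.52 ± 0.12, edgeR adjusted p = 0.0424). Of 17 neuropeptide genes, Penk, Gal, Tac1 and Cartpt rose (median 0.29, camera adjusted p = 0.00988, and adjusted p = 0.36 with an estimated correlation). With the GC and length offsets the neuropeptide list had a camera adjusted p of 0.215. Of 15 genes of the Mrgprd class, Runx1 and Lpar3 fell and 13 did not pass, and 5 were lower adjusted over the list alone. That list's median was -0.27 (camera adjusted p = 0.00977, and adjusted p = 0.651 with an estimated correlation). Runx1, a transcription factor gene of this class, fell from 129 ± 18.7 to 74.7 ± 14.4 CPM (-0.79 ± 0.15, edgeR adjusted p = 0.0191). Mrgprd itself had a log2 fold change of -0.27 ± 0.13 (edgeR adjusted p = 0.206), with 4 of 6 L6S1 libraries lower. Without female L6S1 B and C, Tac1, Trpv1 and Runx1 had edgeR adjusted p of 0.0811, 0.078 and 0.0529, and with the submission as a term Trpv1 and Runx1 had 0.0989 and 0.0562. Leaving out 1 library ended the call of Tac1 in 7 of 12 fits, of Trpv1 in 9, of Runx1 in 5, of Cartpt in 9 and of Lpar3 in 10, with edgeR adjusted p of at most 0.0913, 0.138, 0.0684, 0.144 and 0.108. All 5 passed without female L345 D and without female L6S1 A.

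The lists of oxidative phosphorylation and ribosomal protein genes passed by camera with positive medians, and with the offsets for GC content and length the ribosomal list no longer passed. Of 79 nuclear genes of oxidative phosphorylation, 5 rose, none fell and 74 did not pass, while 36 were higher adjusted over the list alone. The median was 0.36 (camera adjusted p = 8.82e-14, and adjusted p = 0.553 with an estimated correlation), 0.22 with no gene called without female L6S1 B and C, and 0.12 with the GC and length offsets. Ndufa9, a complex I gene, rose from 325 ± 31.2 to 463 ± 77.5 CPM (SD, n = 6; 0.51 ± 0.12, edgeR adjusted p = 0.0472), and its edgeR adjusted p was 0.0681 with the offsets. Leaving out 1 library ended the Ndufa9 call in 10 of 12 fits, all except those without female L345 D or female L6S1 A (edgeR adjusted p at most 0.143). Of 80 cytosolic ribosomal protein genes, none passed alone and 20 were higher adjusted over the list alone. Their median was 0.28 (camera adjusted p = 7.18e-09, and adjusted p = 0.651 with an estimated correlation), 0.16 without female L6S1 B and C, and -0.01 with the offsets, where the camera adjusted p was 0.508. Camera called each of these lists in 57 of 100 splits of the libraries, the real split included, so their passing is weak evidence of a level effect.

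The axon guidance and calcium channel lists passed by camera with negative medians. Of 50 axon guidance genes, Nrp1, Sema4b and Unc5c fell, Sema3a rose and 46 did not pass (median -0.35, camera adjusted p = 0.00282, and adjusted p = 0.553 with an estimated correlation). Nrp1, a semaphorin co-receptor gene, fell from 117 ± 15.1 to 72.2 ± 13.3 CPM (SD, n = 6; -0.69 ± 0.14, edgeR adjusted p = 0.0263). Its call was lost in 6 of 12 fits that left out 1 library (edgeR adjusted p at most 0.0885), and those of Sema4b, Unc5c and Sema3a in 7, 9 and 9 (at most 0.105, 0.105 and 0.0974). All 4 passed without female L345 D and without female L6S1 A. Of 14 voltage-gated calcium channel genes none passed alone, and 4 were lower adjusted over the list alone (median -0.30, camera adjusted p = 0.0178, and adjusted p = 0.553 with an estimated correlation). Without female L6S1 A the calcium channel list had a camera adjusted p of 0.0727. With the GC and length offsets the camera adjusted p was 0.433 for axon guidance and 0.8 for calcium channels.

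Dcn and some immune transcripts were higher at L6S1. Dcn, which encodes the matrix proteoglycan decorin, rose from 64.3 ± 9.72 to 213 ± 70.9 CPM (SD, n = 6; 1.67 ± 0.14, edgeR adjusted p = 1.91e-05) and was the only called gene of 11 fibroblast genes tested (camera adjusted p = 0.217, and 0.0327 by camera without female L6S1 B). The median of the fibroblast list was 0.43, and -0.08 without female L6S1 B and C. Which cells the Dcn reads came from was not tested. Of 8 immune cell genes tested, C1qb and Cd74 rose and 6 were higher adjusted over the list alone. The median was 1.97 (camera adjusted p = 0.000494, and adjusted p = 0.553 with an estimated correlation), and 1.03 without female L6S1 B and C. C1qb, a complement gene, rose from 0.991 ± 0.26 to 4.62 ± 3.18 CPM (2.21 ± 0.38, edgeR adjusted p = 0.00982). Trac, the T cell receptor alpha constant gene, rose from 0.85 ± 0.258 to 4.02 ± 1.36 CPM (2.24 ± 0.28, edgeR adjusted p = 0.000632). Cd74, an antigen presentation gene, had 137 CPM in female L6S1 C and 0.899 to 8.85 CPM in the other 11 libraries. Its call and that of H2-Aa were lost in 8 and 7 of the 12 fits that left out 1 library (edgeR adjusted p at most 0.118 and 0.0889), while both passed without female L6S1 C.

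**Figure D3:**
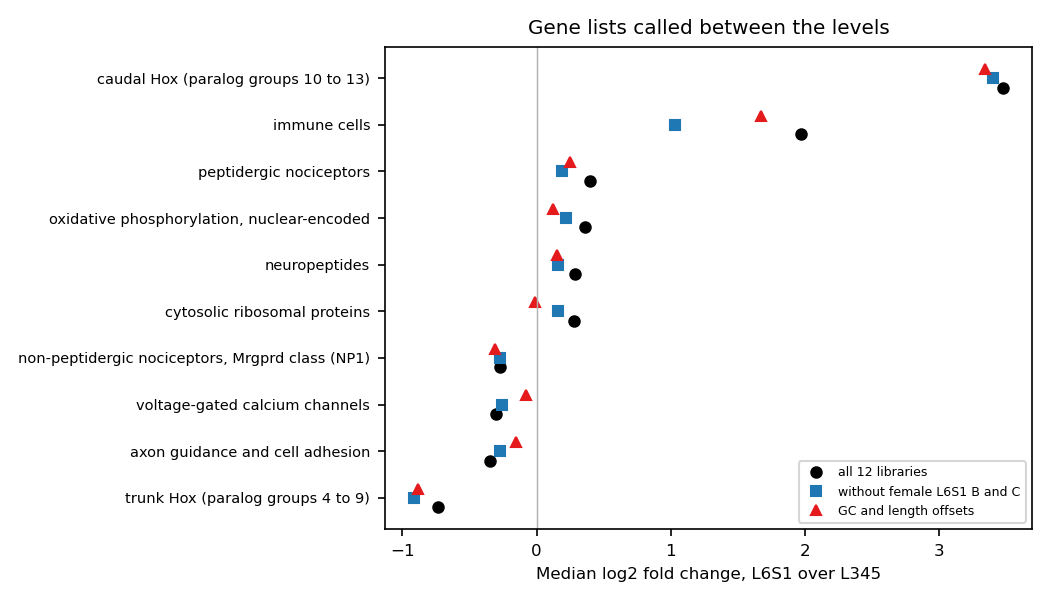
Median log2 fold change (L6S1 over L345, x axis) of the 10 gene lists called between the levels, from all 12 libraries, without female L6S1 B and C, and with GC and length offsets. The caudal Hox list stays at 3.47, 3.4 and 3.34, and the ribosomal protein list moves from 0.28 to 0.16 and -0.01.

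In all, 356 of 15281 genes differed between the levels by the edgeR quasi-likelihood test, 222 higher and 134 lower at L6S1. Of these, 336 were protein coding, 130 changed by more than 1 on the log2 scale, and the median absolute change was 0.80. Without female L6S1 B and C the count was 137, with 111 of the 356 kept. With the GC and length offsets it was 593, with 273 kept. With the submission as a term it was 125 (123 kept), with the glial score as a covariate 89 (71 kept), and within the 8 libraries of the first submission 499 (211 higher, 288 lower; 233 kept). The second submission held 1 L345 library and no male L345 library, so it gave no value of its own. The count was 90, 186 and 84 without male L345 A, B and C, and 80, 83 and 883 without female L345 B, C and D. It was 112, 127 and 128 without male L6S1 A, B and C. Without female L6S1 A it was 4031 (1735 higher, 2296 lower), with the same 356 among them. The limma-voom count was 3268 (1502 higher, 1766 lower), so the excess of higher genes depended on the libraries and the method.

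**Figure D4:**
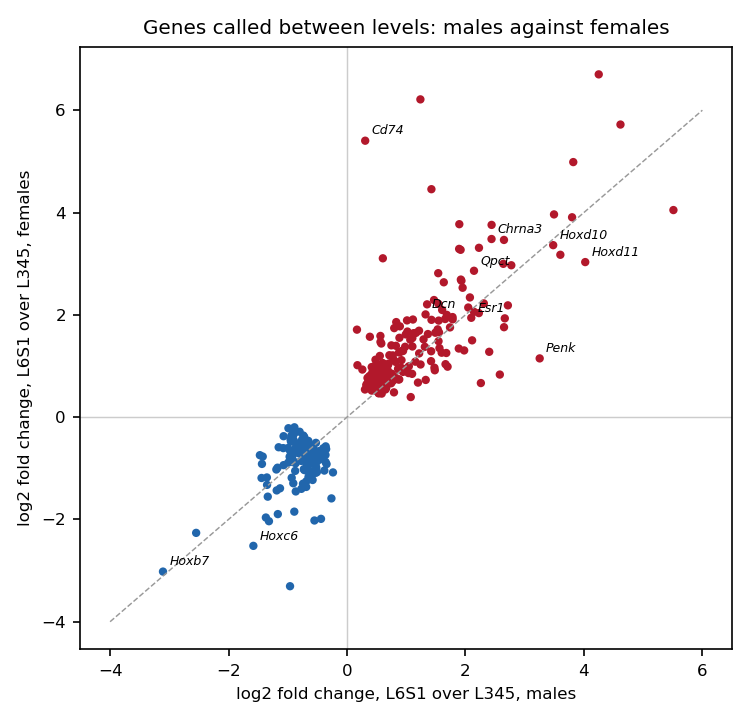
Log2 fold change of L6S1 over L345 in males (x axis) against females (y axis) for the 356 genes called between the levels, red where higher and blue where lower at L6S1; the dashed line marks equal change. Hoxd11 lies at 4.02 in males and 3.03 in females, and Hoxb7 at -3.11 and -3.02.

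The interaction asked whether males and females differed in the level effect, and no gene passed. Penk had the clearest difference among the peptide genes: it stood at 12.2 ± 4.16 and 116 ± 32.4 CPM in male L345 and L6S1, and at 15.3 ± 9.13 and 34.0 ± 5.9 CPM in female L345 and L6S1 (SD, n = 3). Its level effect was 3.25 ± 0.42 in males (edgeR adjusted p = 0.00465) and 1.15 ± 0.39 in females (edgeR adjusted p = 0.14). The interaction of Penk did not pass (edgeR adjusted p = 0.871). Penk was singled out after its values were seen. The smallest p values belonged to a gene with no symbol (ENSMUSG00000048665, chromosome 6, 67165203 to 67165616; log2 difference 4.00, edgeR adjusted p = 0.475) and to Yipf4 (1.65, edgeR adjusted p = 0.871). Sult6b2, Gm5430 and Gm15266 followed at the same edgeR adjusted p of 0.871. The count was 0 by edgeR, with 714 genes at an unadjusted p under 0.05. DESeq2 called 2 genes (ENSMUSG00000048665 and Yipf4), limma-voom 2 and the unfiltered fit 3. Without female L6S1 A, which leaves B and C in that group, edgeR called 817, among them Penk (edgeR adjusted p = 0.044), ENSMUSG00000048665 (0.00451) and Yipf4 (0.00278).

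Within each sex fewer genes passed than over both. In males 34 genes passed (28 higher, 6 lower at L6S1) and in females 55 (47 higher, 8 lower), by edgeR. The male libraries fitted alone gave 211 (93 higher, 118 lower), and the male contrast within the first submission 197 (85 higher, 112 lower), so which direction held more male calls depended on the fit. Gsta4, chosen after its values were seen, had the smallest p in both (edgeR adjusted p = 0.000134 in males and 7.44e-05 in females). Hoxd11 rose by 4.02 in males (edgeR adjusted p = 0.00465) and 3.03 in females (edgeR adjusted p = 0.0132), and Hoxb7 had -3.11 and -3.02 (edgeR adjusted p = 0.000636 and 0.000512). Chrna3 rose by 2.44 in males (edgeR adjusted p = 0.0231) and 3.48 in females (edgeR adjusted p = 0.00171), an interaction of 1.04 that did not pass (edgeR adjusted p = 0.871). The male count was 14, 12 and 16 without male L345 A, B and C, 16 and 9 without male L6S1 B and C, and 60 without female L6S1 C. The female count was 22 and 17 without female L345 B and C, and 3843 (1627 higher, 2216 lower) without female L6S1 A. Without both female L6S1 B and C, the male count was 133 (66 higher, 67 lower) and the female count 24.

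In the comparison of sexes most genes called by edgeR were sex-linked. Of 9 genes called by edgeR (2 higher and 7 lower in females), 7 were Y-linked and lower in females: Ddx3y, Eif2s3y, Kdm5d, Uty, Uba1y, Gm29650 and Gm4017. Xist was higher in females. The pseudogene Gm4017 lies within Ddx3y, so their reads may be shared. DESeq2 called 27 genes (14 higher, 13 lower) and the unfiltered fit 24 (12 higher, 12 lower). The only autosomal call was Prokr2, the gene of a prokineticin receptor (ENSMUSG00000050558, chromosome 2, 132337733 to 132385447). It had 5.57 and 3.24 CPM in male L345 and L6S1 against 8.13 and 9.95 CPM in female L345 and L6S1 (log2 fold change 1.08 ± 0.17, edgeR adjusted p = 0.033). The Prokr2 call was lost in 7 of 12 fits that left out 1 library (edgeR adjusted p at most 0.189), all except those without male L345 C, female L345 B, or female L6S1 A, B or C. Without both female L6S1 B and C its edgeR adjusted p was 0.14, with the GC and length offsets 0.155, with the submission as a term 0.133, in the first submission alone 0.224, and with the glial covariate 0.0791. The Gm4017 call was lost without male L345 B or C, female L345 B or D, or male L6S1 B or C (edgeR adjusted p at most 0.0855).

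By sex, the list of X-linked genes that escape inactivation passed by camera with a positive median: 8 of 8 were positive, Xist passed, and 5 were higher adjusted over the list alone (median 0.52, camera adjusted p = 2.85e-09, and adjusted p = 0.0913 with an estimated correlation). Of 20 interferon response genes none passed alone, 19 were positive and 2 were higher adjusted over the list alone (median 0.37, camera adjusted p = 7.69e-07, and adjusted p = 0.704 with an estimated correlation). Their median was 0.10 without female L6S1 B and C. The immune cell, fibroblast and caudal Hox lists also passed, with medians of 0.74, 0.51 and 0.27 (camera adjusted p = 0.0105, 0.0462 and 0.0462, and adjusted p = 0.974 for each with an estimated correlation). Without female L6S1 B and C their medians were 0.15, 0.01 and 0.34. Without female L6S1 C the adjusted p of these 3 lists was 0.0681, 0.511 and 0.0787 by camera. Leaving out 1 library ended the fibroblast call in 7 of 12 fits (female L345 B, female L6S1 A and C, male L345 B and C, male L6S1 B and C) and the caudal Hox call in 8 (female L345 B and C, female L6S1 A, B and C, male L345 B, male L6S1 A and B). The camera adjusted p in those fits was at most 0.511 and 0.316. At L345 alone 6 genes differed by sex, all sex-linked, and at L6S1 alone 11 differed (5 higher and 6 lower in females) by edgeR. The L6S1 count was 6, 7 and 5 without male L6S1 A, B and C and 2060 without female L6S1 A. The count over both levels was 991 without female L6S1 A and 7 to 11 in the other fits that left out 1 library.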

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

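The gap test was fixed before the data were examined, while 4 of the 56 genes it was run on (Gsta4, Mrap2, Pcsk1 and Srd5a2) were chosen after their values were seen. For the named genes called by level, and for 4 measures of library composition, the gap between an extreme library and its nearest neighbour was divided by the range of the 6 libraries of that level. The ratio passed the critical value of Dixon's test in 9 of 120 groups, and chance passes about 1 in 20. Groups of 3 libraries were not tested.

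At L345, male L345 B was the lowest library for Hoxd10 (log2 CPM 0.137 against 2.65 to 3.12 in the others, ratio 0.842). It was also the lowest for Hoxd11 (-2.08 against 0.497 to 1.52, ratio 0.717) and for Oprd1 (0.0684 against 0.812 to 1.23, ratio 0.638). Female L345 B was the lowest for Hspa1a (1.95 against 3.3 to 3.83, ratio 0.716) and for Pcsk1 (4.22 against 4.64 to 4.86, ratio 0.658). Reads of Hspa1a may be divided with its near-identical copy Hspa1b, and the level call of Hspa1a was lost in 7 of 12 fits that left out 1 library (edgeR adjusted p 0.0547 to 0.0846). Female L345 D was the highest for Dcn (6.37 against 5.85 to 6.04, ratio 0.632).

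At L6S1, female L6S1 C was the lowest library for Hoxc6 (log2 CPM -2.98 against -0.441 to 0.634, ratio 0.703) and the highest for H2-Aa (5.15 against 0.395 to 1.85, ratio 0.694). Female L6S1 B was the lowest for Sema4b (3.81 against 4.56 to 4.99, ratio 0.637).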

How the results depend on the processing

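The fits without both female L6S1 B and C, with GC and length offsets, and of the males alone were chosen after seeing the data; the other alternatives were fixed before the data were examined. Of 61 called results of genes named by the rule, without the 4 genes chosen after their values were seen, 22 kept their direction and call in every alternative, among them 18 of 52 level results. Their 1456 alternative values comprised 1079 with the same call, 377 that no longer passed and none with the opposite sign. Of 214 alternative values of uncalled results, 22 passed and 2 had the opposite sign. Ret by level turned from -0.09 to 0.02 with GC and length offsets and to 0.12 with the glial covariate. In this part the cause was not tested unless stated.

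The level count was 356 (222 higher, 134 lower) and 545 (412 higher, 133 lower) with upper-quartile scaling. With DESeq2 the counts were 1563 by level, 27 by sex, 2 for the interaction, 98 by level in males, 747 in females and 101 by sex at L6S1. With limma-voom they were 3268 by level (1502 higher, 1766 lower), 2 for the interaction, 1864 by level in males, 14 by sex at L345 and 6 at L6S1. Without a filter, which tests 26677 genes, they were 841 by level, 24 by sex, 3 for the interaction, 78 by level in males, 256 in females and 49 by sex at L6S1. With the submission term they were 125 by level, 6 by sex at L6S1, and 3 lists by sex. With the first submission only, which holds 8 libraries, they were 197 by level in males (85 higher, 112 lower) and 5 by sex at L6S1. With the glial covariate they were 89 by level and 20 in males. Without female L6S1 B and C they were 137 by level, 133 in males, 24 in females, 5 by sex at L6S1, and 8 lists by sex. With GC and length offsets they were 593 by level, 64 in males, 85 in females, 17 by sex at L6S1, 6 lists by level and 3 by sex. The male libraries alone gave 211 by level (93 higher, 118 lower). Lists called by level and by sex numbered 10 and 5 with camera, 0 and 0 with an estimated correlation, and 6 and 1 with fry.

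The fits that left out 1 library gave 80 to 4031 genes by level, 7 to 991 by sex and 0 to 817 for the interaction. They gave 9 to 60 by level in males, 17 to 3843 in females, 5 to 7 by sex at L345, 5 to 2060 at L6S1, 9 to 13 lists by level and 3 to 7 lists by sex. Each upper end of 817 genes or more came from leaving out female L6S1 A. The lists by sex numbered 3 without female L6S1 A, 3 without male L6S1 B and 3 without female L6S1 C.

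The replicate letters were checked as a pairing. Deviations of libraries with the same letter correlated at 0.01 to 0.34 over 5 pairs of levels and at -0.13 to 0.31 over 5 pairs of sexes. Of the 10 pairs 7 were over 0.1, and because not all of them were, the letters were not taken as a pairing. In 8 of the 10 pairs the first library correlated best with its own letter, a hint from the data and not the design, and male L345 A and male L6S1 A did not. GC-rich minus GC-poor genes (log2) were negative in every B library (-0.93 to -0.14) and positive in every C library (0.03 to 0.59). The A libraries had both signs (-0.17 to 0.2). A factor shared by libraries of the same letter was therefore not excluded. With the replicate block the counts were 5335 by level (2030 higher, 3305 lower), 5 by sex, 981 for the interaction, 135 by level in males and 4843 in females. Female L6S1 A and female L345 D have no partner of their letter at the other level. The female level effect under the block therefore rested on letters B and C, with the female L6S1 libraries that stood apart from the rest. The level results over both sexes and the interaction under the block depend on it, so they are no measure of what a pairing would show. Male letters each had libraries at both levels, and the male count was 135 with the block against 34 without it. The interaction p under the block was 0.00267 for Penk, 0.000253 for ENSMUSG00000048665 and 0.000378 for Yipf4 (edgeR adjusted p), and the sex p of Prokr2 was 0.489 (edgeR adjusted p).

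Depth limited low genes: 3 counts equal 0.112 to 0.185 CPM, so Hotair, Hoxc11 and Srd5a2 were not measurable in most L345 libraries, and no fold change is given for them. For the interaction, simulated 2-fold changes were recovered in 9.1% of genes, so a difference of that size between the sexes was mostly not detectable.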

Other observations

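The tests of autonomic, peptidergic and leukocyte markers, of the second submission, of random loss and of sex for female L6S1 B and C, and the splits of the libraries were chosen after the results were seen; the GC and length test of those libraries was written before.

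The gene with the smallest p by level was Gsta4, a glutathione transferase gene, with 11.6 ± 1.25 CPM at L345 and 49.6 ± 3.46 CPM at L6S1 (SD, n = 6; log2 fold change 2.10 ± 0.12, edgeR adjusted p = 8.96e-07). It was chosen after its values were seen, as were Mrap2, Pcsk1 and Srd5a2. Mrap2, an accessory protein gene of melanocortin receptors, rose from 4.29 ± 0.62 to 18.7 ± 5.58 CPM, and Pcsk1, a prohormone convertase gene, from 25.6 ± 3.83 to 54.3 ± 12.3 CPM. Srd5a2, which encodes a steroid 5-alpha-reductase, had 0.0633 ± 0.0658 CPM at L345. At L6S1 it had 3.71 ± 0.369 CPM in males and 0.926 ± 0.214 CPM in females (SD, n = 3), and that sex difference did not pass (edgeR adjusted p = 0.136). The level calls of all 4 genes passed in every alternative in which the gene was tested.

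Other classes of sensory neuron did not pass by level as lists. Of 10 genes of the Mrgpra3 itch class and 10 of the Nppb and Sst itch class, none passed (medians 0.19 and 0.06, camera adjusted p = 0.448 and 0.461). The median of the Mrgpra3 class was -0.23 without female L6S1 B and C and -0.12 with the GC and length offsets. Of 11 C low-threshold mechanoreceptor genes, Fxyd6 rose and Piezo2 fell (camera adjusted p = 0.865), calls lost in 10 and 6 of 12 fits that left out 1 library (edgeR adjusted p at most 0.147 and 0.0993; both passed without female L345 D or female L6S1 A). Satellite glia and Schwann cell lists did not pass (medians -0.16 and -0.36, camera adjusted p = 0.645 and 0.341), and no gene of either list passed. Without female L6S1 C the Schwann cell list had a camera adjusted p of 0.0419.

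Female L6S1 B and C stood apart from the other 10 libraries, with a typical deviation of 0.551 and 0.642 (log2) against at most 0.303. GC and length bias alone does not account for this, since the lower deviation was still 0.437 with the offsets, against at most 0.199 in the others. The second submission as a whole stays open, since of its other libraries male L6S1 C (0.303) lay above every library of the first submission (at most 0.246) and female L345 D (0.194) did not, and so does sex at L6S1, where female L6S1 A (0.142) is the only other library and the only one of the first submission. Random loss is argued against for the genes low in both: independent draws among genes of like abundance would make 4.8 genes more than 4-fold low in both (95% upper bound 9.0), and 84 of 8314 were, with shorter transcripts (median 2001 against 3496 bases) and more GC (54.1 against 48.8%) than all genes. A loss of RNA or cells shared by these 2 pools may remain too. Thinned to 16176436 counts each, female L6S1 C had reads in 18962 genes and female L6S1 B in 19271. The other libraries had 19330 to 20028, so both were lowest, but B lay close to the others and this does not decide it.

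Chrna3 and Chrnb4 are also genes of autonomic neurons, which pelvic dissections might bring along. Summed over 9 autonomic markers the L6S1 libraries had at most 2.18 CPM, while the lowest Chrna3 level there was 17.5 CPM, which argues against that source. A larger share of all peptidergic neurons would raise the peptidergic list by about as much, and its median log2 change was 0.40 (0.19 without female L6S1 B and C) against 2.31 for Chrnb4. A hypothesis that stays open is a peptidergic subset with both genes that is more frequent, or expresses them more, at L6S1. It was not tested, and no value here ties either gene to peptidergic neurons.

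The immune genes split into a part in 1 library and a part in all. In female L6S1 C, 9 of 11 leukocyte markers were at least 2-fold above every other library, with a sum of 50.7 CPM against at most 4.31, so leukocytes that passed the EGFP gate are a candidate source there. Lyz2 alone gave 32.5 CPM of that sum. The markers outside the 9 were Trbc2 and Ptprc, and Ptprc had 0.242 CPM there against 1.11 CPM in female L6S1 B. In the other 5 L6S1 libraries the sum rose by only 0.92 CPM over L345 (2.04 ± 0.613 to 2.96 ± 0.856, SD), less than C1qb (2.35) or Trac (2.76) alone, which argues against leukocytes as their source. Expression of both genes in neurons, or other transcripts that overlap them, stay open and were not tested.

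Of 100 splits of the 12 libraries, 1 gave at least 356 genes by level, the real split, and the highest other gave 1. The real grouping thus stood out, but a split that mixes the levels spreads genes such as caudal Hox over both groups. The low counts of other splits therefore do not show how many of the 356 calls are due to chance. Nor do they exclude the submission, which was divided unevenly between the levels. For the sex count 1 of 100 gave at least 9 and the highest other gave 1. All of these 9 genes except Prokr2 are Xist or Y-linked. A split that mixes the sexes spreads those genes over both groups, so this outcome was fixed in advance and does not test Prokr2. For the interaction (0 genes) 100 of 100 gave as many and the highest other gave 9, and since no split can give fewer than 0, this decides nothing. For the level in males (34), in females (55), and for sex at L345 (6) and at L6S1 (11), only 10 splits exist, too few for a share under 0.05. In each of these 1 split, the real one, gave as many, and the highest other gave 0. Chance was not excluded for the counts of lists: 21 of 100 splits gave at least 10 lists by level (highest other 14), and 68 of 100 at least 5 by sex (highest other 16). Of single lists, caudal Hox had so small a camera p by level in 1 of 100 splits, trunk Hox and neuropeptides in 2, peptidergic genes in 5, immune cells in 7, oxidative phosphorylation and calcium channels in 9, the Mrgprd class in 10, axon guidance in 11 and ribosomal proteins in 17. By sex the X-linked list had 1 of 100, interferon and immune cells 6, caudal Hox 18 and fibroblasts 24. The X-linked list holds Xist, which mixed splits spread over both groups, so its share was largely set in advance and does not test its other members. Camera called these lists in 9 to 57 of 100 splits by level and in 25 to 41 by sex, so a camera call alone is weak evidence.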
